A study of Homo sapiens with 8 samples.

How the data were processed

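RNA from MCF7 cells, an estrogen receptor-positive human breast cancer line, was measured on 8 single-colour Agilent arrays of a custom human design. Per the labels, cells in hormone-stripped medium received ethanol vehicle, estrogen, epigallocatechin gallate (EGCG, the main catechin of green tea) or estrogen together with EGCG for 24 h. Groups and replicate numbers were taken from the sample titles, with 2 arrays in each of the 4 groups. Doses were not given in the sources used here. The labels do not say that the replicates of a group came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

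Each scanner file holds spot intensity values in arbitrary linear units, which the authors obtained with Feature Extraction 10.7.3.1, per the file headers. They also hold the median brightness of the local background and 0 or 1 flags for each spot. Per the labels' design text, the authors took median spot signals, subtracted background with normexp, normalised by quantiles and fitted linear models. The submitters' processing notes name limma without a version. The deposited value table holds log2 values, and its normexp offset is not stated in the labels. A setting with offset 16, quantile normalisation and no subsequent centring matched it with a mean correlation of 0.999999 across probes and a median absolute difference of 0.00334. Its array medians lie between 6.897 and 6.908, so scale and direction are those of log2 signal.

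For the values reported here, median signals were background-corrected with normexp (offset 50), using the local background, in limma 3.58.1 under R 4.3.3. Control spots were removed after that step (1319 of them), leaving 51538 spots of 50238 probes. Log2 values were then quantile-normalised between arrays. Spots marked as non-uniform or population outliers were set to missing, which affected between 66 and 383 spots per array. The 130 probes printed on 11 spots each were averaged. A probe was tested when it was well above background on both arrays of at least 1 group, which kept 37475 probes.

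Gene symbols came from matching the accession given for each probe to the RefSeq gene table without version numbers (28595 probes), or otherwise by current symbol (2998) or by synonym (1176). The remaining 17469 probes kept the name in the file and were left out of gene-level summaries. Of the tested probes, 26310 had a symbol, and they covered 16707 genes. Each gene was represented by its probe with the highest mean signal over the 8 arrays. Values of other probes of a named gene are given where they differ widely.

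The 8 arrays lay on 1 slide and were scanned as 1 batch, so no slide or scan effect could be fitted. The 4 arrays without EGCG occupied row 1 of the slide and the 4 with EGCG row 2, with each group in neighbouring positions. Within each row the arrays without estrogen lay at positions 1 and 2 and those with estrogen at positions 3 and 4. Slide row and EGCG therefore cannot be told apart, nor can position in the row and estrogen. Arrays carry no read depth, and their number limits the precision. Between 71.08% and 75.78% of probes were well above background on 7 of the arrays, and 57.94% on array 1 of estrogen with EGCG. No spot was saturated.

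All 8 arrays entered 1 limma model with a mean per group and 4 residual degrees of freedom, moderated by eBayes (prior 2.987 degrees of freedom). The comparisons were estrogen vs vehicle, EGCG vs vehicle, estrogen with EGCG vs estrogen, estrogen with EGCG vs EGCG, and the interaction. The interaction is the EGCG effect with estrogen minus the EGCG effect without it. P-values were adjusted by Benjamini-Hochberg over probes, with a threshold of 0.05, and all are two-sided. Errors given with log2 changes are moderated standard errors with n = 2 arrays per group. They use 1 spread per probe pooled over all 8 arrays, so they do not measure the spread of the compared groups alone.

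Before the data were examined, 25 gene lists were fixed. They cover estrogen-induced and estrogen-repressed genes, the estrogen receptor and its cofactors, DNA replication, mitosis, ribosome biogenesis, ribosomal proteins, NRF2 targets, the ATF4 stress response, chaperones of the endoplasmic reticulum (ER), heat shock, targets of the aryl hydrocarbon receptor (AhR), cholesterol and fatty acid synthesis, hypoxia and glycolysis, p53 targets, the BCL2 family, metal response, interferon-stimulated genes, NF-kB targets, immediate early genes, DNA methylation and telomerase, and markers of mesenchymal, luminal epithelial and other cell types. Lists were tested with camera (preset correlation 0.01) on 1 probe per gene measured on every array, adjusted over the lists of a comparison. An estimated correlation and fry were alternatives. The estimate lay below the preset for some lists that lost their call. For hypoxia and glycolysis, whose call was lost for estrogen vs vehicle, it was -0.00034. A call lost with an estimated correlation therefore does not by itself show correlation between members. In these texts a member rose or fell where its probe passed the threshold over all probes, and a count adjusted over the list alone is given beside it.

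The rule for named genes was also fixed beforehand. For each pairwise comparison it takes up to 10 genes with the largest rise and 10 with the largest fall among genes that passed the threshold, with both arrays of a group measured and beyond both of the other. For the interaction it takes 5 and 5. Where none passed, the 5 with the smallest p are named as not passing. ESR1, PGR, GREB1, TFF1, PDZK1, CXCL12, CCND1 and MYC are given throughout, with up to 4 members of each described list, and uncharacterised loci are left out of the ranks. Genes named outside this rule are said to have been chosen after their values were seen.

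The linear model was tested on simulated values for estrogen vs vehicle on 37475 probes. It recovered 26% of changes of 1 log2 unit and 91% of changes of 2 units, with 3 false calls among 120. A simulated shift of the mitosis list was called with adjusted p = 1.52e-21, and 0 of the other 24 lists were. The simulated values had the same spread in every group and no correlation between genes. In the real data the SD between replicates was 0.3551 for vehicle and 0.1164 for estrogen. The simulation therefore does not show how often false calls of probes or lists arise in the real data.

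Alternatives planned beforehand were normexp offset 16, no background correction, mean signals, processed signals scaled to their 75th percentile, 75th percentile scaling, cyclic loess, no detection filter, detection on every array, the replicate number as a block, the compared groups alone, trended and robust moderation, 1 probe per gene, the deposited table, and leaving out each array. Added after seeing the data were removal of each array's trend with probe GC content, array quality weights, and averaging the estrogen arrays into 1 sample.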

Results

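Gene expression was profiled in MCF7 cells after 24 h of vehicle, estrogen, EGCG or estrogen with EGCG, with 2 arrays per group. MCF7 cells proliferate in response to estrogen, and the series asks how the tea polyphenol EGCG affects estrogen-regulated genes. Replicate arrays correlated at r = 0.9809 for vehicle, 0.9979 for estrogen, 0.986 for EGCG and 0.9924 for estrogen with EGCG, across probes, which are not independent replicates. The corresponding standard deviations between replicates were 0.36, 0.12, 0.30 and 0.23 log2 units. On 64 bright probes printed in 11 copies, the estrogen arrays differed by 0.0999 log2 (SD) against 0.0691 from the scatter of the copies. The same difference was 0.615 for vehicle, 0.443 for EGCG and 0.26 for estrogen with EGCG. The estrogen pair thus differed little more than repeated spots, with 20% of 130 such probes beyond the limit that 5% exceed by chance. The first principal component held 50.8% of the variance and placed array 2 of EGCG and both arrays of estrogen with EGCG apart from the other 5 arrays.

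With estrogen, 21 of 40 genes fixed beforehand as estrogen-induced rose against vehicle. GREB1, an estrogen-induced growth regulator, rose by 3.73 ± 0.18 log2 (13.2-fold, adjusted p = 0.00117). PDZK1, a scaffold protein, rose by 3.62 ± 0.14, the transcription factor genes MYBL1 and EGR3 by 3.51 ± 0.14 and 3.13 ± 0.22, the chemokine gene CXCL12 by 2.59 ± 0.18 and the progesterone receptor gene PGR by 2.47 ± 0.17. PSCA, which encodes a cell surface antigen, fell by 2.88 ± 0.23 (adjusted p = 0.00485), and the protease inhibitor gene CSTA fell by 2.25 ± 0.25.

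Of the 40 measured estrogen-induced genes, 21 rose and 0 fell (35 rose adjusted over the list alone), with a median change of 1.21. Of the 22 estrogen-repressed genes, 10 fell (20 adjusted over the list alone), with a median of -0.998. TGFB3, encoding a growth factor, fell by 1.77 ± 0.19. NEDD9, an adhesion scaffold gene, fell by 1.57 ± 0.16 on its representative probe, while its other probes gave 0.01 and 0.12. BMF, a pro-apoptotic gene, fell by 1.65 ± 0.29. Other large rises were those of PLAT, the tissue plasminogen activator gene (2.71 ± 0.16), and the cadherin gene CDH26 (2.74 ± 0.12). The pseudogenes PDZK1P1 (3.51 ± 0.15) and POM121L8P (3.18 ± 0.17) also rose, and their probes may share transcripts with near-identical genes. Other large falls were those of IGFBP3 (-2.27 ± 0.36, with another probe at -0.07), CACNG6 (-1.92 ± 0.13), the retinaldehyde reductase gene DHRS3 (-1.87 ± 0.18), RASSF2 (-1.82 ± 0.14), GABRP (-1.81 ± 0.17) and HOXB2 (-1.79 ± 0.19, with another probe at 0.02). Other probes gave 1.63 for GREB1, from 0.72 to 2.23 for MYBL1, from 0.02 to 2.54 for CXCL12, 1.27 for CDH26, 0.31 for POM121L8P, -1.64 for PSCA and -0.39 for TGFB3.

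In the DNA replication list 17 of 34 members rose (29 adjusted over the list alone, median 0.90), among them the ribonucleotide reductase subunit RRM2 (1.52 ± 0.22), E2F1 (1.36 ± 0.14), EXO1 (1.34 ± 0.12) and the helicase subunit MCM7 (1.33 ± 0.16). In the mitosis list 12 of 30 rose (28 adjusted over the list alone, median 0.96), including the spindle checkpoint kinase BUB1B (1.27 ± 0.15), KIF2C (1.21 ± 0.17), topoisomerase TOP2A (1.17 ± 0.15) and CDK1 (1.11 ± 0.14). In ribosome biogenesis 2 of 20 rose, BOP1 (0.76 ± 0.13) and NOP56 (0.76 ± 0.14), and 11 adjusted over the list alone (median 0.47). These 3 lists and the estrogen-induced and estrogen-repressed lists passed camera, and their calls held with an estimated correlation (adjusted p from 0.00608 to 0.0297).

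A further 6 lists passed camera with the preset correlation, but their calls were lost with an estimated correlation. Of 8 AhR targets, 4 fell and 1 rose (5 and 1 adjusted over the list alone, median -0.84, adjusted p = 0.243 with an estimated correlation). AHRR (-1.83 ± 0.26), the quinone reductase gene NQO1 (-1.31 ± 0.17) and ALDH1A3 (-1.28 ± 0.16) fell, and TIPARP rose by 1.07 ± 0.13. Of 21 p53 targets, TP53INP1 (-1.53 ± 0.18) and BTG2 (-1.20 ± 0.19) fell (3 adjusted over the list alone, median -0.26, adjusted p = 0.212 with an estimated correlation). Of 22 interferon-stimulated genes 0 passed (2 lower adjusted over the list alone, median -0.38, adjusted p = 0.0964 with an estimated correlation), with IFIT1 at -0.93 ± 0.21 and MX1 at -0.84 ± 0.17. Of 23 hypoxia and glycolysis genes, the enolase gene ENO2 rose by 0.98 ± 0.18 (7 adjusted over the list alone, median 0.29, adjusted p = 0.0964 with an estimated correlation). Of 17 NF-kB targets, TNF rose by 0.89 ± 0.14, with another probe at 0.07 (4 higher adjusted over the list alone, median 0.12, adjusted p = 0.243 with an estimated correlation). Of 10 metal response genes 0 passed (5 higher adjusted over the list alone, median 0.97, adjusted p = 0.224 with an estimated correlation), with the metallothionein genes MT1E at 1.47 ± 0.38 (another probe at -0.12) and MT1H at 1.34 ± 0.31. Metallothionein genes are near-identical, so their probes may cross-hybridise.

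The other 14 lists did not pass, with adjusted p from 0.0823 to 0.836 and between 0 and 2 members of each past the threshold. Their medians were 0.26 for heat shock, 0.25 for cholesterol synthesis, 0.15 for DNA methylation and telomerase, 0.13 for ER chaperones, 0.09 for immediate early genes, 0.08 for markers of other cell types, 0.06 for mesenchymal markers and 0.03 for fatty acid synthesis. They were -0.01 for the ATF4 stress response, -0.06 for NRF2 targets, -0.07 for ribosomal proteins, -0.09 for the BCL2 family, -0.12 for the estrogen receptor and its cofactors and -0.14 for luminal markers. For mesenchymal markers the test pointed lower despite the positive median, and for markers of other cell types the mean was -0.09. The estrogen receptor gene ESR1 (-0.40 ± 0.16, other probes -0.13 and 0.00), MYC (1.00 ± 0.21, adjusted p = 0.0736) and the cyclin gene CCND1 (0.35 ± 0.37) did not pass. TFF1, another known estrogen target, was among the brightest genes in every group (18.1 log2 with vehicle), with a difference of 0.05 ± 0.19 (another probe 0.54) that did not pass.

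In total, 517 probes were higher and 287 lower with estrogen (limma, adjusted p under 0.05). Of these, 276 and 138 changed at least 2-fold, and 338 genes were higher and 178 lower. The total of 804 fell to 13 when the estrogen arrays were averaged into 1 sample, and to 56 when these groups were fitted alone. It ranged from 12 to 1232 when single arrays were left out, being 12 and 25 without estrogen arrays 1 and 2, 371 without vehicle array 2, 306 and 312 without arrays 1 and 2 of estrogen with EGCG, and 1232 and 1224 without EGCG arrays 1 and 2.

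**Figure D1:**
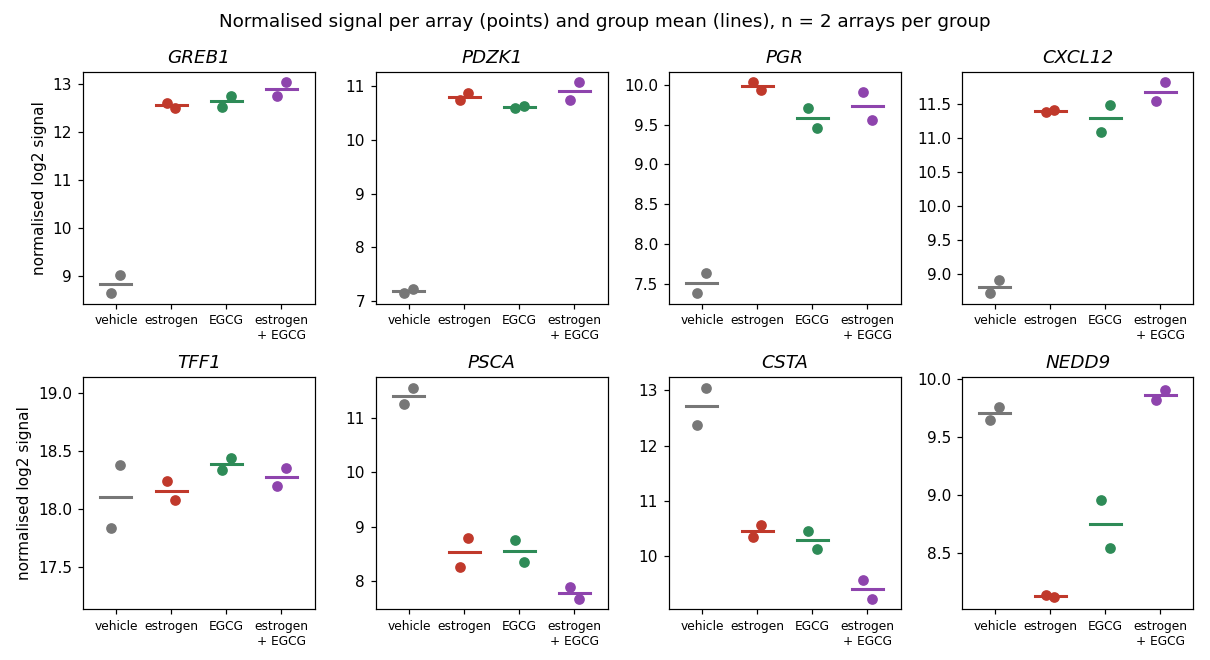
Normalised log2 signal (vertical axes, ranges differ between panels) of 8 genes on each array, with points for the 2 arrays of a group and lines for group means. GREB1, PDZK1, PGR and CXCL12 lay higher, and PSCA and CSTA lower, on the 6 treated arrays than on the vehicle arrays, while TFF1 overlapped between groups and NEDD9 was lowest with estrogen alone.

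With EGCG alone, 17 of the 40 estrogen-induced genes rose against vehicle. GREB1 rose by 3.81 ± 0.18 log2 (14-fold, adjusted p = 0.00127), PDZK1 by 3.44 ± 0.14, MYBL1 by 3.09 ± 0.14, EGR3 by 2.90 ± 0.22, CXCL12 by 2.48 ± 0.18 and PGR by 2.07 ± 0.17. Further rises were seen for IGSF1 (2.66 ± 0.21), CDH26 (2.30 ± 0.12), the matrix protein gene MGP (2.30 ± 0.29), PDZK1P1 (3.30 ± 0.15) and POM121L8P (2.41 ± 0.17). PSCA fell by 2.85 ± 0.23 (adjusted p = 0.00747), CSTA by 2.41 ± 0.25 and HOXB2 by 1.89 ± 0.19. Other probes gave 1.32 for GREB1, from 0.56 to 1.73 for MYBL1, from -0.13 to 1.85 for CXCL12, 0.96 for CDH26, 1.59 and 2.40 for IGSF1, 0.00 for POM121L8P, -1.58 for PSCA and -0.04 for HOXB2. PLA2G10 (-1.87 ± 0.25), AHRR (-1.85 ± 0.26), CACNG6 (-1.83 ± 0.13), DHRS3 (-1.76 ± 0.18), RASSF2 (-1.72 ± 0.14), CFAP206 (-1.69 ± 0.20, another probe -0.85) and GABRP (-1.68 ± 0.17) fell as well.

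Of the 40 estrogen-induced genes, 17 rose with EGCG (34 adjusted over the list alone, median 1.24), and of the 22 estrogen-repressed genes 6 fell (19 adjusted over the list alone, median -0.85), including TP53INP1 (-1.38 ± 0.18), TGFB3 (-1.23 ± 0.19, another probe -0.11) and TGFB2 (-1.19 ± 0.20, another probe -0.26). DNA replication had 14 of 34 members higher (31 adjusted over the list alone, median 0.89), with RRM2 at 1.80 ± 0.22, MCM7 at 1.40 ± 0.16, CDC45 at 1.31 ± 0.15 and EXO1 at 1.27 ± 0.12. Mitosis had 10 of 30 higher (27 adjusted over the list alone, median 0.996), with TOP2A at 1.55 ± 0.15, BUB1B at 1.41 ± 0.15, KIF2C at 1.29 ± 0.17 and AURKA at 1.29 ± 0.22. Hypoxia and glycolysis had 3 of 23 higher (9 adjusted over the list alone, median 0.36), namely lactate dehydrogenase LDHA (1.35 ± 0.20), ENO2 (1.30 ± 0.18) and the mitophagy gene BNIP3 (1.13 ± 0.15). In ribosome biogenesis 0 of 20 passed and 8 were higher adjusted over the list alone (median 0.42), with NOP56 at 0.74 ± 0.14. These 6 lists passed camera with a preset and with an estimated correlation (adjusted p from 0.00732 to 0.0222).

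Another 9 lists passed with the preset correlation and not with an estimated one. Of 8 AhR targets, AHRR and ALDH1A3 (-1.33 ± 0.16) fell and TIPARP rose by 0.84 ± 0.13 (5 and 1 adjusted over the list alone, median -0.66, adjusted p = 0.196 with an estimated correlation). Of 21 p53 targets, TP53INP1 fell (2 adjusted over the list alone, median -0.18, adjusted p = 0.27 with an estimated correlation). The interferon-stimulated list had 0 of 22 members past the threshold (2 lower adjusted over the list alone, median -0.40, adjusted p = 0.0877 with an estimated correlation), with IFIT1 at -0.94 ± 0.21 and MX1 at -0.90 ± 0.17. Heat shock genes had a median of 0.42 with 0 of 14 past the threshold (2 higher adjusted over the list alone, adjusted p = 0.274 with an estimated correlation), with HSPA4L at 0.74 ± 0.15 and AHSA1 at 0.71 ± 0.18. For DNA methylation and telomerase the median was 0.20 with 0 of 12 past the threshold (3 higher adjusted over the list alone, adjusted p = 0.27 with an estimated correlation), with UHRF1 at 1.01 ± 0.22 and the methyltransferase gene DNMT1 at 0.74 ± 0.19. Cholesterol synthesis (0.28), fatty acid synthesis (0.21), NF-kB targets (0.22) and metal response (0.59) had positive medians with 0 members past the threshold (0, 1, 0 and 1 higher adjusted over the list alone). Their adjusted p with an estimated correlation was 0.167, 0.196, 0.221 and 0.314. CCND1 (1.19 ± 0.37), MYC (0.97 ± 0.21), ESR1 (-0.58 ± 0.16, other probes 0.02 and 0.18) and TFF1 (0.28 ± 0.19, another probe 0.65, or -0.01 for the first with 75th percentile scaling) did not pass.

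With EGCG alone, 351 probes were higher and 173 lower (222 and 110 genes), 211 and 87 of them at least 2-fold. The total of 524 became 208 with processed signals, 325 with the replicate number as a block, 119 with array quality weights, 29 with the estrogen arrays averaged and 0 when EGCG and vehicle were fitted alone (3055 at an unadjusted p under 0.05). Without single arrays it ranged from 23 to 1592, and each of the 8 moved it by more than 1.5 times. It was 1397 and 125 without vehicle arrays 1 and 2, 29 and 23 without estrogen arrays 1 and 2, 1592 and 238 without EGCG arrays 1 and 2, and 73 and 71 without arrays 1 and 2 of estrogen with EGCG.

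Both comparisons use the same vehicle arrays, so they share chance values. Of the calls, 300 probes were higher in both and 139 lower in both, overlaps that the shared arrays raise by an amount that was not estimated. The sign with EGCG matched that with estrogen for 515 of the 516 higher calls measured in both and for 286 of 287 lower calls. Selecting these calls on a change against the same vehicle arrays favours a matching sign. Over all probes the sign matched for 73%, against 66.6% in simulated unchanged groups with equal spreads. The real spreads were unequal, with an SD between replicates of 0.3551 for vehicle and 0.1164 for estrogen. The matching share for unchanged groups with such spreads was not simulated. The 73% therefore does not show matching signs beyond those that the shared vehicle arrays give. Across 36681 probes measured on every array the changes correlated at r = 0.749, while the shared vehicle arrays alone would give 0.719 for unchanged groups with their own replicate spreads. The covariance was 0.103 against 0.06 for unchanged groups. With the changes taken against different vehicle arrays, the correlation was 0.177 and, the other way round, 0.272. The average effects of estrogen and of EGCG correlated at r = 0.721 across 37403 probes, and at 0.4 without array 1 of EGCG. Their errors are also correlated where the groups differ in spread between replicates, as they did here. A change confined to estrogen with EGCG enters both averages alike and raises their correlation. The correlation therefore does not measure whether estrogen and EGCG act alike.

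**Figure D2:**
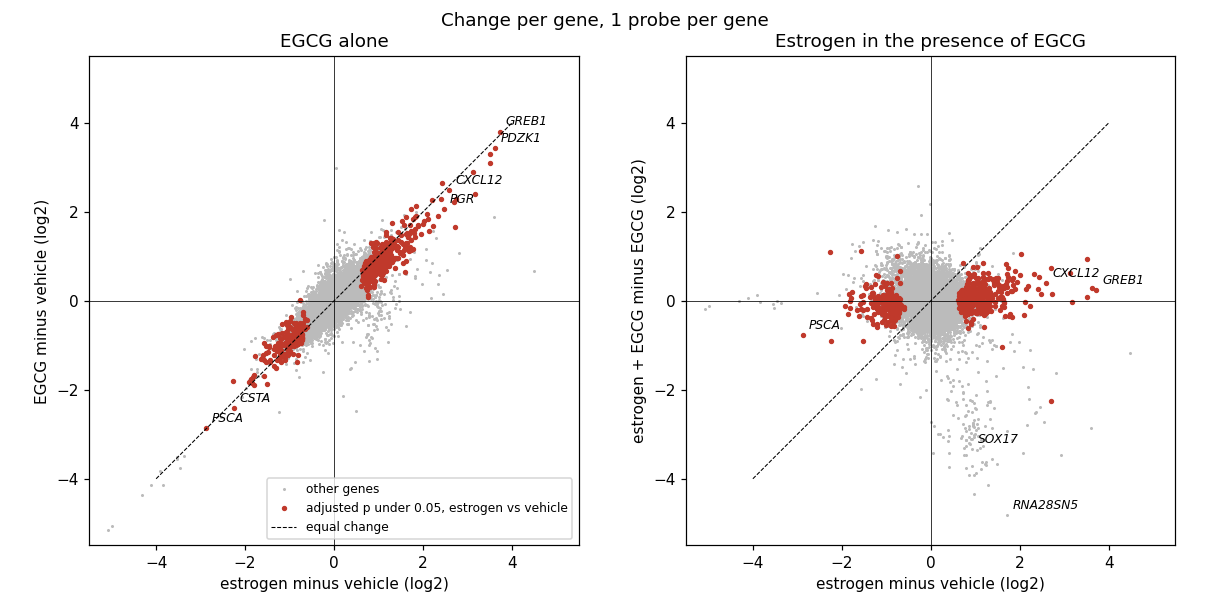
Log2 change per gene with estrogen against vehicle (horizontal axes) and, on the vertical axes, with EGCG against vehicle (left) or with estrogen and EGCG against EGCG (right), red where estrogen vs vehicle passed adjusted p 0.05. Red genes followed the line of equal change on the left and lay near 0 on the right, where a separate set of grey genes that includes RNA28SN5 and SOX17 lay low.

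Adding estrogen to EGCG, compared with EGCG alone, gave 0 probes past the threshold (limma, smallest adjusted p = 0.18), with 4603 at an unadjusted p under 0.05. The estrogen targets did not pass. The difference was 0.25 ± 0.18 for GREB1 (adjusted p = 0.557), 0.28 ± 0.14 for PDZK1, 0.39 ± 0.18 for CXCL12 and 0.15 ± 0.17 for PGR, so rises of the size seen with estrogen alone lay outside these errors. ESR1 was at 0.28 ± 0.16, MYC at 0.33 ± 0.21, CCND1 at 0.83 ± 0.37 and TFF1 at -0.11 ± 0.19. The genes with the smallest p did not pass, with adjusted p = 0.353 for each, and were NEDD9 (1.11 ± 0.16), PDIA3 (1.01 ± 0.14), MYBL1 (0.94 ± 0.14), PALB2 (0.90 ± 0.13) and NDUFA11 (-0.96 ± 0.13). Other probes gave 0.12 and 0.88 for NEDD9, -0.46 for GREB1, from -0.22 to 0.30 for CXCL12, -0.26 and -0.18 for ESR1, -0.31 for MYC and 0.12 for TFF1. Trended and robust moderation called 1 probe, of SGCD (2.58), named here after its value was seen. The ribosomal RNA genes RNA28SN5 and RNA18SN5, also chosen after their values were seen, were at -4.81 and -3.12 and did not pass.

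In this comparison 11 lists lay higher by camera with the preset correlation, with 0 members past the threshold over all probes. Their medians were 0.32 for estrogen-induced genes (1 of 40 higher adjusted over the list alone), 0.36 for the estrogen receptor and its cofactors, 0.33 for heat shock, 0.26 for DNA methylation and telomerase, 0.22 for luminal markers, 0.21 for mitosis and for cholesterol synthesis, 0.20 for DNA replication, 0.19 for ribosome biogenesis (1 of 20 higher adjusted over the list alone), 0.17 for hypoxia and glycolysis and 0.12 for interferon-stimulated genes, with 0 members higher adjusted over the list alone in the other 9. With an estimated correlation 0 lists passed (adjusted p from 0.254 to 0.294), as with fry. The number of lists fell to 4 with processed signals (median of all probes -0.106), to 3 with 75th percentile scaling and to 3 without array 1 of EGCG. Calls of single probes appeared when arrays were left out, 252 and 223 without EGCG arrays 1 and 2 and 218 without array 2 of estrogen with EGCG.

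Across probes, the estrogen effect without EGCG and that with EGCG, which share no arrays, correlated at r = -0.206 with a slope of -0.215. The correlation was -0.0142 without array 2 of vehicle and -0.115 without array 2 of EGCG. Among the 516 probes higher with estrogen, 61% also had a positive change in the presence of EGCG, with a median of 0.08 against 1.05. Among the 287 lower probes, 57.8% had a negative change, with a median of -0.06 against -0.98.

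Adding EGCG to estrogen, compared with estrogen alone, gave 37 genes higher and 12 lower. The 8 genes given throughout did not pass, with CCND1 at 1.68 ± 0.37 (adjusted p = 0.0598). It passed without either vehicle array or either EGCG array (adjusted p from 0.0217 to 0.0472). GREB1 was at 0.33 ± 0.18 (adjusted p = 0.251), CXCL12 at 0.29 ± 0.18, PDZK1 at 0.10 ± 0.14, PGR at -0.25 ± 0.17, MYC at 0.31 ± 0.21, TFF1 at 0.12 ± 0.19 and ESR1 at 0.10 ± 0.16. Other probes gave -0.77 for GREB1, from -0.39 to -0.24 for CXCL12, -0.69 for MYC and -0.24 and 0.13 for ESR1. PDZK1 was at -0.18 with processed signals, TFF1 at -0.66 with processed signals and -0.56 with 75th percentile scaling, and ESR1 at -0.05 with the latter. PDIA3, a protein disulfide isomerase gene of the ER, rose by 1.80 ± 0.14 (adjusted p = 0.0195), with other probes at 0.67 and 0.79. NEDD9, the 1 member of the estrogen-repressed list past the threshold here, rose by 1.73 ± 0.16 (adjusted p = 0.0207), while its other probes gave -0.32 and 0.67. In the same comparison RNA28SN5 was at -5.58 and RNA18SN5 at -4.43 without passing (adjusted p = 0.0645 and 0.0611), and RNA28SN5 also differed between the vehicle arrays (18.3 and 15.1).

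The remaining largest rises were P4HA1, a collagen prolyl hydroxylase gene (1.67 ± 0.22), the RNA-binding protein gene HNRNPU (1.59 ± 0.19, with other probes from -1.03 to 1.40), PRDM6 (1.55 ± 0.17), the BRCA2 partner gene PALB2 (1.504 ± 0.13), the splicing factor gene SRSF9 (1.47 ± 0.18), CDCA4 (1.47 ± 0.15), the proteasome subunit gene PSMD6 (1.30 ± 0.15) and the deubiquitinase gene USP8 (1.27 ± 0.12). The largest falls were PSORS1C2 (-5.27 ± 0.27), SOX8 (-4.52 ± 0.17) and SLC34A3 (-3.31 ± 0.26). Their probes have 65%, 75% and 70% GC against a median of 43.3% over tested probes. They carried an outlier flag on 3, 3 and 2 of the 8 arrays, against 0.377% of values over tested probes. Flagged values were set to missing. Both arrays of the compared groups were measured, but the errors of these probes rest on fewer arrays than those of most others. Other probes of PSORS1C2 gave -0.34 and 0.80, and another of SOX8 gave -0.13. AQP10 (-2.003 ± 0.25, another probe -0.07), the calcium-binding protein gene S100A9 (-1.12 ± 0.13), PLP2 (-1.08 ± 0.14), the respiratory complex gene NDUFA11 (-1.04 ± 0.13), PLAAT4 (-0.96 ± 0.13) and TOMM20L (-0.94 ± 0.12) also fell.

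By camera with the preset correlation 14 lists passed, 13 of them higher, with an estimated correlation 0 did, and with processed signals or 75th percentile scaling 2 did. Hypoxia and glycolysis had a median of 0.40 with P4HA1 past the threshold (6 of 23 adjusted over the list alone, adjusted p = 0.218 with an estimated correlation). The next lists had 0 members past the threshold over all probes. The estrogen receptor and its cofactors had a median of 0.43, luminal markers 0.39, the ATF4 stress response 0.33, DNA methylation and telomerase 0.32, estrogen-induced genes 0.31, DNA replication 0.23, cholesterol and fatty acid synthesis 0.21 each and NRF2 targets 0.15. Adjusted over the list alone, 3, 0, 4, 3, 2, 6, 0, 3 and 2 of their members were higher, and 2 of the ATF4 list and 1 of DNA replication lower. Each of these 9 had adjusted p = 0.218 with an estimated correlation. Heat shock had a median of 0.40 and ER chaperones of 0.34 (adjusted p = 0.279 with an estimated correlation for each), and mitosis of 0.20 (adjusted p = 0.302 with an estimated correlation), with 4, 0 and 1 members higher adjusted over the list alone. Members with large values that did not pass were the thioredoxin reductase gene TXNRD1 (2.10 ± 0.45), CELSR2 (1.79 ± 0.25), the chaperone genes HSPA5 (1.78 ± 0.45, another probe 0.05) and HSP90AA1 (1.34 ± 0.31, other probes from -0.21 to 0.98), CCND1 (other probes 0.23 and 1.90), UHRF1 (1.17 ± 0.22) and TOP2A (0.92 ± 0.15). The metal response list lay lower, with a median of -1 and 0 of 10 members past the threshold (6 lower and 2 higher adjusted over the list alone, adjusted p = 0.377 with an estimated correlation). MT1E was at -1.87 ± 0.38, with another probe at 0.04, and MT1H at -1.56 ± 0.31.

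The comparison called 97 probes higher and 26 lower (37 and 12 genes), against 11446 at an unadjusted p under 0.05, and the split became 812 higher and 1450 lower with 75th percentile scaling, 1022 and 1261 without vehicle array 1, and 946 and 1176 without vehicle array 2. The total of 123 became 0 with processed signals (median of all probes -0.169), with the replicate number as a block and with the estrogen arrays averaged, and 11292 when these groups were fitted alone. Without single arrays it ranged from 0 to 5262, being 0 and 5 without estrogen arrays 1 and 2, 1 and 373 without arrays 1 and 2 of estrogen with EGCG, 2283 and 2122 without vehicle arrays 1 and 2, and 5262 and 5203 without EGCG arrays 1 and 2. Log2 changes of all probes fell with probe GC content (Spearman -0.224 across probes), with a median of -0.51 for the 848 probes above 60% GC. The same correlation was -0.255 for estrogen with EGCG vs EGCG and -0.243 for the interaction. It was 0.135 for estrogen vs vehicle and 0.0429 for EGCG vs vehicle.

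The EGCG effect without estrogen and that with estrogen correlated at r = 0.284 across probes, with a slope of 0.434. The correlation was -0.000507 without array 2 of EGCG, 0.139 without array 1 of vehicle and 0.427 without array 1 of EGCG. Of the calls, 3 probes were higher in both against 0.91 for independent lists, and 1 was lower in both against 0.102. The higher ones were probes of ARHGAP11A, FOSL2 and an unnamed transcript, and the lower one of SPRED3, named here after their values were seen.

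The interaction tested whether the effect of estrogen differed between cells with and without EGCG. It was negative for several estrogen targets and passed for 6 of the 40 estrogen-induced genes over all probes. It was -3.47 ± 0.25 for GREB1 (adjusted p = 0.0137), -3.34 ± 0.20 for PDZK1, -2.57 ± 0.19 for MYBL1, -2.50 ± 0.31 for EGR3, -2.32 ± 0.24 for PGR (adjusted p = 0.037), -2.20 ± 0.25 for CXCL12 and -1.59 ± 0.19 for E2F1. PDZK1P1 (-3.43 ± 0.21), POM121L8P (-3.21 ± 0.24) and CDH26 (-2.58 ± 0.16) were among the lowest as well. Other probes gave -2.09 for GREB1, from -1.64 to -0.26 for MYBL1, from -2.24 to -0.24 for CXCL12, -0.56 for POM121L8P and -0.98 for CDH26. It was positive for NEDD9 (2.68 ± 0.22, with its other probes at 0.00 and 0.87), RASSF2 (1.82 ± 0.20), CACNG6 (1.81 ± 0.18), the ganglioside synthase gene ST3GAL5 (1.81 ± 0.19, another probe 0.74) and PDIA3 (1.78 ± 0.19, other probes 0.72 and 0.76). ESR1 (0.68 ± 0.23, other probes -0.26 and -0.05), CCND1 (0.49 ± 0.52, other probes -0.45 and 0.69), MYC (-0.67 ± 0.30) and TFF1 (-0.16 ± 0.27, another probe -0.42) did not pass.

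Of the 40 estrogen-induced genes 6 had a negative interaction (25 adjusted over the list alone, median -0.94), and of the 22 estrogen-repressed genes 1, NEDD9, had a positive one (16 adjusted over the list alone, median 0.91). DNA replication had a median of -0.76 with E2F1 past the threshold (18 of 34 adjusted over the list alone). These 3 lists passed camera with a preset and an estimated correlation (adjusted p from 0.0259 to 0.0263). Mitosis (-0.73), metal response (-1.45), AhR targets (0.60), the estrogen receptor and its cofactors (0.47), interferon-stimulated genes (0.43), luminal markers (0.36) and p53 targets (0.24) passed with the preset correlation alone, with 0 members past the threshold. Adjusted over the list alone, 15 mitosis and 5 metal response genes were lower, 4 AhR targets were higher and 1 lower, and 4 interferon-stimulated and 3 p53 genes were higher. Their adjusted p with an estimated correlation was 0.116, 0.27, 0.311, 0.239, 0.116, 0.239 and 0.311.

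The interaction was positive for 24 probes and negative for 42, with 6306 at an unadjusted p under 0.05, and processed signals gave 4 and 23 (median of all probes -0.128). Positive ones were the more numerous without array 1 of EGCG (494 and 194), array 2 of estrogen with EGCG (90 and 19), array 1 of vehicle (73 and 57) and array 2 of vehicle (21 and 16). The total of 66 became 10 with the replicate number as a block and 0 with the estrogen arrays averaged. Without single arrays it ranged from 0 to 688, being 0 and 1 without estrogen arrays 1 and 2, 4 and 109 without arrays 1 and 2 of estrogen with EGCG, 130 and 37 without vehicle arrays 1 and 2, and 688 and 354 without EGCG arrays 1 and 2.

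**Figure D3:**
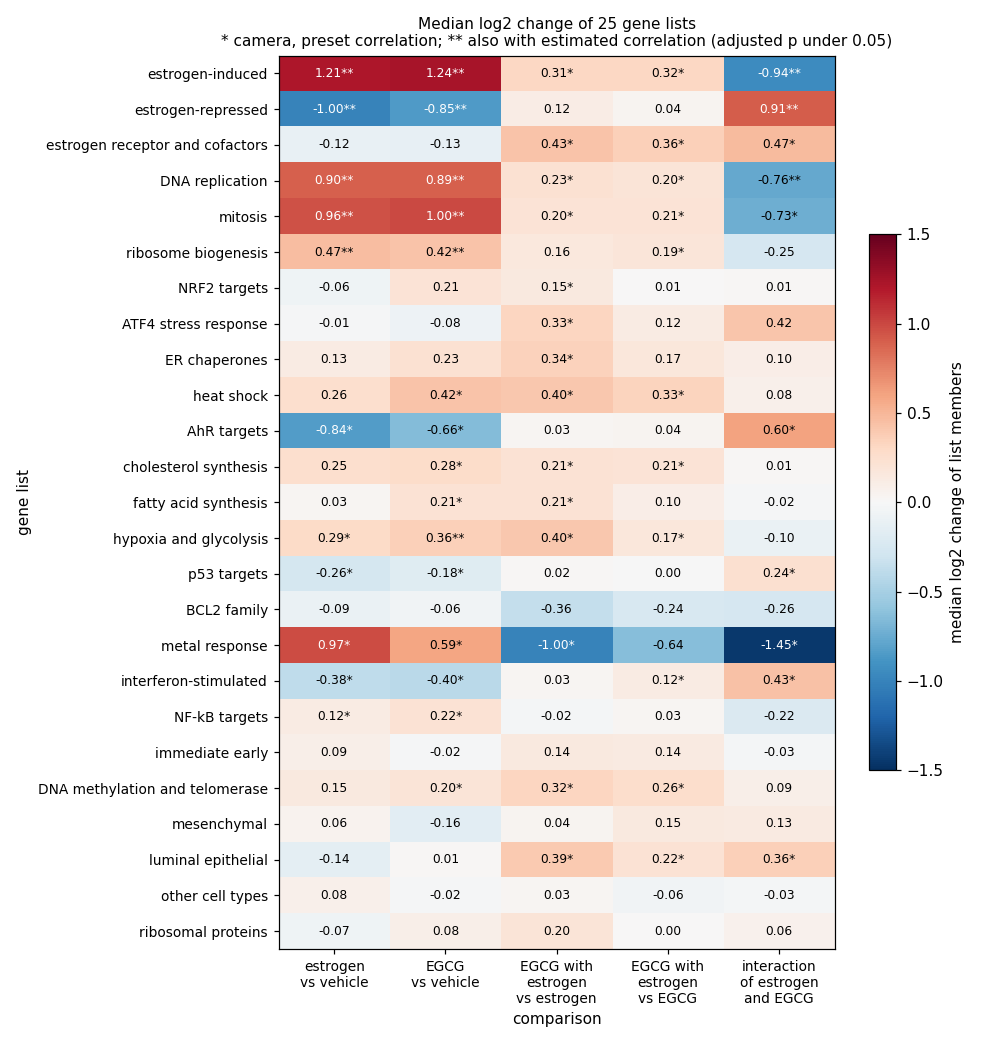
Median log2 change of the measured members of 25 gene lists (rows) in 5 comparisons (columns), red for higher and blue for lower, with marks for lists past adjusted p 0.05 in camera. The first 2 columns match in direction for estrogen-induced (1.21 and 1.24) and estrogen-repressed genes (-0.998 and -0.851), and the interaction column opposes them (-0.94 and 0.91). The interaction subtracts both of those changes and uses the same vehicle arrays, so its direction is not independent of theirs.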

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

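The tests in this part were chosen after the results were seen, apart from the interaction itself. The interaction of estrogen and EGCG was planned, and it singled out these results because the effect of estrogen differed between the groups with and without EGCG: 66 probes differed in their estrogen effect with and without EGCG. By gene it was -3.47 for GREB1, -3.43 for PDZK1P1, -3.34 for PDZK1, -3.21 for POM121L8P and -2.58 for CDH26, and 2.68 for NEDD9, 1.82 for RASSF2, 1.81 for CACNG6, 1.81 for ST3GAL5 and 1.78 for PDIA3, in log2 units. By list it gave medians of -0.94 for estrogen-induced genes, 0.91 for estrogen-repressed genes, 0.47 for the estrogen receptor and its cofactors, -0.76 for DNA replication, -0.73 for mitosis, 0.60 for AhR targets, 0.24 for p53 targets, -1.45 for metal response, 0.43 for interferon-stimulated genes and 0.36 for luminal markers. With an estimated correlation the calls of the estrogen-induced, estrogen-repressed and DNA replication lists held, and those of the other 7 were lost (adjusted p from 0.116 to 0.311).

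The first pattern is that EGCG alone carried the change seen with estrogen, so that estrogen added little on top. The mean of the estrogen-induced list was 11.48 and 11.37 on the vehicle arrays and from 12.73 to 13.13 on the other 6. Changes taken against different vehicle arrays correlated at 0.913 and 0.955 over the genes of the estrogen-induced and estrogen-repressed lists. Chance values of the shared vehicle arrays thus do not account for the pattern in these lists. The lists change in opposite directions, so r partly reflects direction, and over all probes it was 0.177 and 0.272. If EGCG left the estrogen-induced list unchanged, a swap giving EGCG arrays estrogen-treated cells would leave an estrogen-labelled array at vehicle level. The lowest such array lay 1.25 log2 above the higher vehicle array. This does not test an exchange of vehicle with EGCG arrays, or among the 6 arrays other than vehicle. The mean change of the list with EGCG was 1.02 times that with estrogen, which an estrogen-like action of EGCG and estrogen present in the EGCG wells (or EGCG samples exchanged with outside ones) both predict, so these cannot be told apart here. An estrogenic action of EGCG remains a hypothesis, and a contrast of EGCG with estrogen found by limma 0 probes higher and 1 lower (of BC042553, -5.13, with 1787 at an unadjusted p under 0.05), which does not show that they act alike, as the 95% interval was from -0.81 to 0.01 for PGR and, before adjustment over probes, from -0.75 to -0.09 for MYBL1 (adjusted p = 0.819 for each).

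The relation of the average effects (r = 0.721) was as large in absolute value in 4 of 100 relabellings of the 8 arrays, the real one included, with a highest other value of 0.778. That share is under 0.05 but excludes chance weakly at most. The relabellings are a sample, they assume like spreads in the groups, which differed, and r was 0.4 without array 1 of EGCG. A change confined to estrogen with EGCG also raises r, so the test does not bear on whether estrogen and EGCG act alike.

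The second pattern is the set of differences between estrogen with EGCG and estrogen alone. The average trend of each array with probe GC content is argued against as its whole cause, since removing it gave 379 called probes, including 122 of the 123. That removal does not cover a GC-linked signal that differs between probes of like GC content, which was not tested. Array 1 of estrogen with EGCG had a poor background (a negative control SD of 4.812 against 2.049 to 2.274 on the others). This is argued against as the sole source of the differences over all probes, since array 2 of that group lay farther from estrogen. The SD of its change across probes was 1.22 times that of array 1. That SD covers all probes, so it does not test the called ones. Among probes well above background on every array, 121 of the 123 calls were kept. The calls were lost when array 1 was left out, which leaves a lone sample in that group. PDIA3 was then at 1.94 against 1.80 and SOX8 at -4.60 against -4.52. How far the calls depend on array 1 thus stays open. A difference that also arises between replicates of a single treatment stays open too. Array 2 minus array 1 of EGCG correlated at 0.512 over all probes with the difference between estrogen with EGCG and estrogen alone. Over the called probes, which are selected for low replicate spread, the correlation was 0.276. The interaction tests whether the effect of EGCG depends on estrogen. It passed for 66 probes, and for 0 with the estrogen arrays averaged, so an effect of EGCG that needs estrogen remains open. The slide row, which EGCG shares, remains open and untested.

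The third pattern is the steep falls led by PSORS1C2, SOX8 and SLC34A3 with EGCG beside estrogen. Other probes of PSORS1C2 and SOX8 fell by at most -0.343 log2, which is consistent with signal of single probes for these genes, while SLC34A3 has no other probe and was not covered. Of 146 genes falling by more than 2 log2 (5 of them past the threshold, with AQP10 and SPRED3 as the others), 118 were measured on both vehicle arrays, which this fall does not use, and 92.4% of these were lower on array 2 than on array 1 of vehicle, against 45.2% of genes overall. Their median difference there was -2.88, and their probes had a median GC content of 70% against 45%, although those of RNA28SN5 and RNA18SN5, which fell steeply too, have 45%. A technical signal that varies between arrays is therefore a candidate explanation for these falls, GC content does not cover each of them, and no biological explanation was tested.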

How the results depend on the processing

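Removal of the GC trend, array quality weights and averaging of the estrogen arrays were chosen after seeing the data, and the others beforehand. Among the values of named genes under the alternatives, 3076 kept their direction and side of the threshold, 694 kept their direction and lost the call, 84 gained a call and 11 reversed. Among those of called lists, 1132 kept their call and 210 lost it, with 0 reversed. The 11 belong to genes that had not passed the threshold.

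The causes of the values that follow were not tested, except where the design gives them. Averaging the estrogen arrays, or fitting EGCG and vehicle alone, leaves the log2 changes of EGCG vs vehicle as they were. Its counts then moved only through the estimated spread and its degrees of freedom. The calls of EGCG vs vehicle in the main fit thus depend on the other groups as well. With offset 16, estrogen with EGCG vs estrogen gave 61 probes and the interaction 40. Processed signals gave 533 for estrogen, 208 for EGCG, 0 for estrogen with EGCG vs estrogen (12329 at an unadjusted p under 0.05), 27 for the interaction, 2 and 4 lists for estrogen with EGCG vs estrogen and vs EGCG, and a correlation of average effects of 0.592. With them estrogen with EGCG vs estrogen was -0.1756 for PDZK1 and -0.6578 for TFF1. With 75th percentile scaling that comparison gave 2262 probes, with TFF1 at -0.5553 and ESR1 at -0.04606. The lists were 2 and 3 for estrogen with EGCG vs estrogen and vs EGCG, and TFF1 was -0.01163 with EGCG vs vehicle. Cyclic loess gave 6 lists for estrogen with EGCG vs estrogen.

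For estrogen with EGCG vs estrogen, detection on every array gave 1675 probes, 1 probe per gene 39, the deposited values 30, removal of the GC trend 379 and array quality weights 11590. For the interaction, the deposited values gave 31 and removal of the GC trend 120. For EGCG vs vehicle array weights gave 119. With the compared groups alone, estrogen gave 56, EGCG 0 and estrogen with EGCG vs estrogen 11292. With the estrogen arrays averaged, the counts were 13, 29, 0 (5466 at an unadjusted p under 0.05) and 0 for the interaction. Trended and robust moderation gave 1 for estrogen with EGCG vs EGCG.

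The replicate number as a block gave 325 for EGCG, 0 for estrogen with EGCG vs estrogen (11675 at an unadjusted p under 0.05) and 10 for the interaction. Differences between replicates correlated across probes at 0.32 between EGCG and estrogen with EGCG, and at 0.27 between vehicle and estrogen with EGCG. For the other pairs of groups the correlation lay between -0.051 and 0.012. Whether replicate numbers pair arrays therefore stays open. With an estimated correlation 5, 6, 0, 0 and 3 lists were called for estrogen, EGCG, estrogen with EGCG vs estrogen, vs EGCG and the interaction, and fry called 0 for estrogen with EGCG vs EGCG.

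Leaving out each array in turn leaves a lone sample, which is assumed to vary like the other groups. Counts then ranged from 12 to 1232 for estrogen, 23 to 1592 for EGCG, 0 to 5262 for estrogen with EGCG vs estrogen, 0 to 252 vs EGCG and 0 to 688 for the interaction, with 3 to 11 lists vs EGCG. The estrogen effects without and with EGCG correlated between -0.276 and -0.0142, the EGCG effects without and with estrogen between -0.000507 and 0.427, and the average effects between 0.4 and 0.771. Signs turned for genes that were not called, with ranges from -0.2293 to 0.3238 for TFF1 (-0.0233 without array 1 of estrogen) and -0.06977 to 0.7558 for CCND1 with estrogen, -0.06579 to 0.2697 for PDZK1 in estrogen with EGCG vs estrogen, -0.02284 to 0.3244 for PGR vs EGCG, and -0.4423 to 0.1157 for TFF1 in the interaction. Signal over background limits array 1 of estrogen with EGCG, where 57.94% of probes were well above background.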

Other observations

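The contents of this part were chosen after the values were seen. The set that fell steeply with EGCG beside estrogen included the probes of ribosomal RNA. RNA28SN5, the large-subunit ribosomal RNA gene, was at 18.3 and 15.1 log2 on the vehicle arrays, 18.4 on both estrogen arrays, 18.3 and 16.98 on the EGCG arrays, and 14.7 and 11 on the arrays of estrogen with EGCG. RNA18SN5 followed with 13.1 and 11.1, 13.9 and 14.0, 14.0 and 11.3, and 10.3 and 8.76. NEUROG1 (-5.43) and SOX17 (-5.32) had log2 changes near that of RNA28SN5 (-5.58) between estrogen with EGCG and estrogen alone. These 4 genes did not pass the threshold (adjusted p from 0.0611 to 0.0651).

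The vehicle arrays each held isolated bright genes. On array 1 of vehicle 4 genes and on array 2 of vehicle 6 genes exceeded every other array by more than 6 log2, and on each of the other 6 arrays 0 genes did.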
